A study of Mus musculus with 8 samples.

How the data were processed

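Gene expression was measured in liver of 8 male C57BL/6 mice aged between 92 and 101 days. The labels assign 4 mice to the heterozygous genotype, with 1 intact copy of Mtap, and 4 to the wild-type genotype. RNA was isolated with TRIzol and labelled with biotin, per the labels' protocols, and hybridised to Affymetrix whole-genome mouse arrays, 1 array per mouse. The deposited values are log2 signals per probe set made by the authors with RMA (background correction, quantile normalisation and probe summarisation), as the submitters' processing notes name RMA. The version, software and settings of RMA are not given in the sources used here. The log2 scale was taken from the values, which ran from 1.64 to 14.7 over the arrays with medians from 3.91 to 3.97. RMA is known to compress differences of weakly expressed transcripts, so folds of probe sets near the lowest signals are likely too small. The precision is limited by the number of arrays, and no detection calls were used.

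The table held 45101 probe sets. The 64 control probe sets were left out of all tests, which left 45037. The platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160. Of those with 1 symbol, 34741 were matched by gene ID to an NCBI RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. The sources name no genome build, so that table was used only for names, chromosomes and neighbouring genes. Each of 18193 genes was represented by the probe set with the highest mean over the 8 arrays among those with exactly 1 symbol. For 9010 genes this meant choosing among several probe sets, and the report gives other probe sets that disagreed for genes past the threshold and, in 1 place, for further named genes.

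The values were used as deposited. Heterozygous and wild-type livers were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with genotype as the sole term. P-values were adjusted by the Benjamini-Hochberg method over all genes, and separately over all probe sets, with a threshold of 0.05. Adjusted p-values of single genes come from this limma fit unless another is named. Single values per animal were compared with exact two-sided permutation tests over the 70 assignments of 4 against 4, for which 0.0286 is the smallest possible p. Named were Mtap, the genes past the threshold, further genes of smallest p up to 10 in each direction, up to 4 members of smallest p in each gene list, genes near Mtap with an unadjusted p under 0.05, and sex-linked genes as a check of the labels. Outside this rule Asns, Cd163 and Dusp1, which moved most against their called lists, and Cry1, Nr1d2, Tef and Saa3 were named after their values were seen.

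The 40 gene lists comprised 39 hand-written lists and the genes within 10 Mb of Mtap. They covered methionine salvage and the methionine cycle, polyamine, folate, purine, arginine methylation, lipid, bile acid, glucose and xenobiotic metabolism, the circadian clock, sex-biased genes, growth, stress and inflammatory responses, liver zones, markers of other cell types and hand-listed chromosome 4 genes. Each was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 40 lists, and again with a correlation estimated per list and with fry. These lists, the tests and the rule for named genes were fixed before the data were examined.

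Alternatives were the mean of a gene's probe sets, leaving out probe sets of the cross-hybridising kinds, a filter on dim genes, eBayes with trend and robust settings, array weights, renewed quantile normalisation, centring, the replicate number as a block, each array left out in turn, other thresholds and other windows around Mtap. A further 3 alternatives were chosen after seeing the data. A clock score, the mean of evening-phase clock genes minus that of night-phase clock genes, was used as a covariate. The difference between 3' and 5' signals of the Actb and Gapdh control probe sets was used as another. Finally, all 35 splits of the 8 arrays into 4 and 4 were fitted, and the split other than the genotypes with most called genes was used as a block. That block was picked by the expression values themselves and is no recorded batch, so fits with it show how far the calls lean on the array structure and do not correct for a known factor. An earlier comparison of control signals between both sides of that split was discarded, because the sides had been chosen by the outcome. No collection time, hybridisation date or batch was given in the sources used here.

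The gene-level test was checked on simulated data for this comparison, with 18193 genes, 200 of them changed, in 20 runs. It recovered 31.9% of genes changed by 0.5 log2 units, 86.1% of those changed by 1 unit, 96.5% at 1.5 units and 98.5% at 2 units, and 4.54% of its calls were false. Camera called a simulated shift of the heat shock list by 0.3 units in 20 of 20 runs, and called 4 of 780 unshifted lists. On the real arrays, splits with both genotypes equally on each side called from 0 to 12 of the same lists. The simulation drew noise independently for each gene, without the structure of the real arrays, where the highest other split called 215 genes. With 200 genes changed its calls also needed a less strict p than in the real comparison, where 9 genes were called. The simulated rates of recovery and of false gene and list calls therefore do not describe these arrays.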

Results

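Liver expression profiles were compared between 4 male mice heterozygous for Mtap and 4 wild-type males. Mtap encodes methylthioadenosine phosphorylase, which returns the methylthioadenosine left over from polyamine synthesis to methionine and adenine. The comparison asks which transcripts differ in liver when 1 copy of Mtap is lost. All values are RMA log2 signals, and changes are heterozygous minus wild-type. Nothing in the labels says more of the animals than genotype, sex, strain and age. The p-values set the difference between genotypes against the spread within genotypes and treat the 8 livers as independent. Whether animals of 1 genotype shared a litter, collection time or batch is unknown.

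Mtap itself was lower in every heterozygous liver. Its 4 probe sets fell to 57.6% (95% interval 49.4 to 67.0), 49.9% (43.5 to 57.4), 32.2% (23.1 to 44.9) and 35.3% (26.4 to 47.2) of the wild-type level. The groups did not overlap at any of them (exact permutation p = 0.0286 each, the smallest possible with n = 4 per group). The representative probe set averaged 6.90 ± 0.12 (SD, n = 4) in heterozygous and 7.69 ± 0.10 in wild-type liver, a log2 change of -0.80 with an adjusted p of 0.0281 from limma. Which part of the gene the altered allele lacks was not given in the sources used here, so whether each probe set lies outside it is unknown. The adjusted p of this probe set was between 0.0512 and 0.121 when any 1 of heterozygous replicates 1, 3 and 4 or wild-type replicates 1, 2 and 3 was left out, while its log2 change stayed between -0.84 and -0.74. Over the 8 livers the signals of the Y-linked genes were 8.09 to 9.03 (Eif2s3y), 4.91 to 5.78 (Kdm5d) and 4.28 to 5.43 (Uty), and Xist lay between 3.74 and 4.09. Eif2s3y was far above the array medians (3.91 to 3.97) in every liver. The lowest Uty signals lay close to those medians, and without detection calls they do not show expression.

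**Figure D1:**
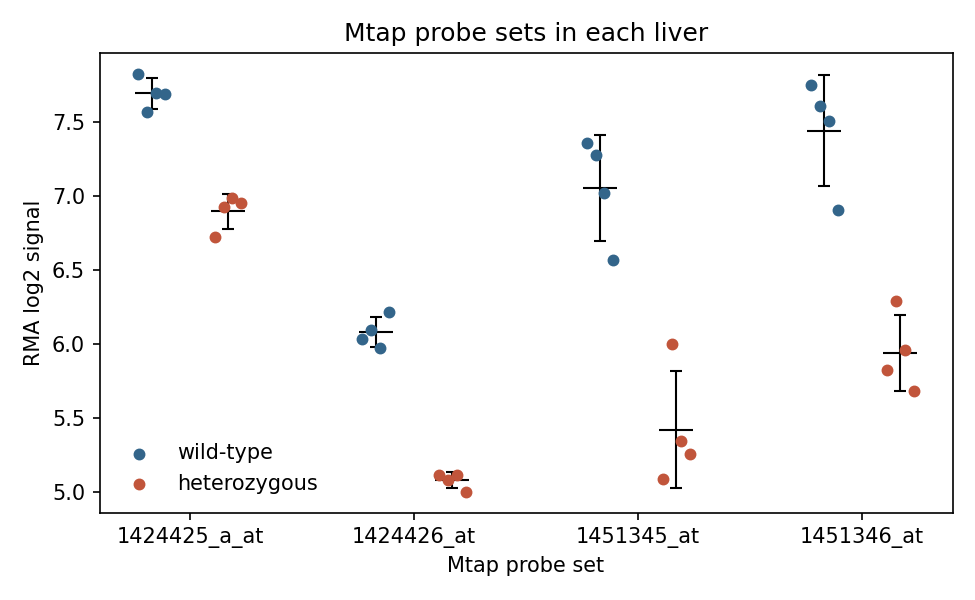
RMA log2 signal (vertical axis) of the 4 Mtap probe sets (horizontal axis) in each liver, with points for animals and bars for the group mean and SD (n = 4). At each probe set all heterozygous livers lie below all wild-type livers, with group means of 6.90 and 7.69 for the representative probe set at the left.

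Beyond Mtap few single genes passed the threshold. Of 18193 genes 9 were called, 5 higher and 4 lower in heterozygous liver. Among these 9, Megf9, a membrane protein with EGF-like domains, rose most, by 2.88 ± 0.25 log2 units (SE), a 7.37-fold difference (adjusted p = 0.00188). Also higher were Gm4274 (1.87 ± 0.18, adjusted p = 0.00271), Upp2, a liver uridine phosphorylase (1.62 ± 0.20, adjusted p = 0.0189), 2310067E19Rik (0.93 ± 0.10, adjusted p = 0.0124) and Arap2 (0.81 ± 0.11, adjusted p = 0.0357). Lower besides Mtap were Trmt9b, a relative of tRNA methyltransferases (-1.39 ± 0.12, adjusted p = 0.00188), Lgalsl, a galectin-like protein (-0.96 ± 0.13, adjusted p = 0.0424), and Dnajb9, a co-chaperone of the endoplasmic reticulum (-0.93 ± 0.13, adjusted p = 0.0448). At an unadjusted p under 0.05 limma listed 1662 genes where chance gives 909.65, and the groups did not overlap for 4.64% of genes where chance gives 2.86%.

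These calls differed in how firmly they stood. Megf9 passed under 18 of 19 alternatives and Gm4274 and Trmt9b each under 17 of 18, the exception being the clock score covariate, under which 0 genes passed. Upp2 passed under 12 of 19, 2310067E19Rik under 12 of 18, Mtap under 9 of 19, Arap2 and Dnajb9 under 7 of 19 each and Lgalsl under 5 of 19, so the last 4 were lost under most. A filter on dim genes removed Gm4274, Trmt9b and 2310067E19Rik before testing, and left 2 calls, Megf9 and Upp2. The count was 3 without heterozygous replicate 1, 5 without wild-type replicate 1, 4 without wild-type replicate 2, 5 without wild-type replicate 3 and 20 without wild-type replicate 4. With the array split described below as a block it was 4, namely Megf9, Gm4274, 2310067E19Rik and Trmt9b, and Mtap had an adjusted p of 0.0915 at a log2 change of -0.79. A second probe set of Megf9 lay near the lowest signals and changed by 0.04, and 1 of the 2 other Arap2 probe sets changed by 0.33 and the other by -0.02, none past the threshold. The second Lgalsl probe set changed by -0.99, the second Trmt9b probe set by -0.41, and the other Upp2 probe sets by 1.62 and 0.75. At the level of probe sets 16 of 45037 passed, 11 higher and 5 lower, among them all 4 of Mtap and 2 with no gene name.

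Genes next in order of p did not pass. On the higher side these were Noct, a deadenylase-family protein with a daily rhythm (1.25), Il13ra1 (0.85), the clock gene Per3 (0.98), Zbed6 (0.64) and Rasgef1b (0.71), with adjusted p between 0.11 and 0.121. On the lower side were Rnd1 (-0.91), Clpx, a subunit of a mitochondrial protease (-0.87), Insig2, a regulator of sterol synthesis (-1.09), Slc45a3 (-0.73), Pdk4, a kinase that restrains pyruvate oxidation (-1.49), and Gmppb (-0.78), all with an adjusted p of 0.11. All 3 probe sets of Insig2 were lower, by 0.98 to 1.09 log2 units in size (values -1.09, -0.99 and -0.98). For some named genes other probe sets differed from the one given, with 0.005 for Clpx, -0.08, 0.66, 0.27, 0.50 and 0.09 for Per3, 0.28 for Zbed6 and 0.15 to 0.68 for Il13ra1, and, of genes near Mtap, -0.20 to 0.26 for Nfia, -0.08 for Rps6, 0.11 for Zdhhc21, -0.02 to 0.71 for Ttc39b, 0.01 for Zfp352 and 0.07 and -0.21 for Eqtn.

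The arrays carried a structure that crossed the genotypes. On the first principal component of all probe sets, with 28.3% of the variance, heterozygous replicates 1, 3 and 4 and wild-type replicate 4 scored between -24.91 and -23.43, and the other 4 arrays between 3.58 and 35.57. Heterozygous replicate 2 stood apart on the second component (-44.12). The difference between 3' and 5' control signals, a sign of RNA integrity and labelling, ranged from 0.713 in heterozygous replicate 2 to 1.12 in heterozygous replicate 3. Its mean differed by 0.0447 between heterozygous and wild-type arrays, within the spread of SD 0.195 and 0.0658 (n = 4 each, exact permutation p = 0.743).

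**Figure D2:**
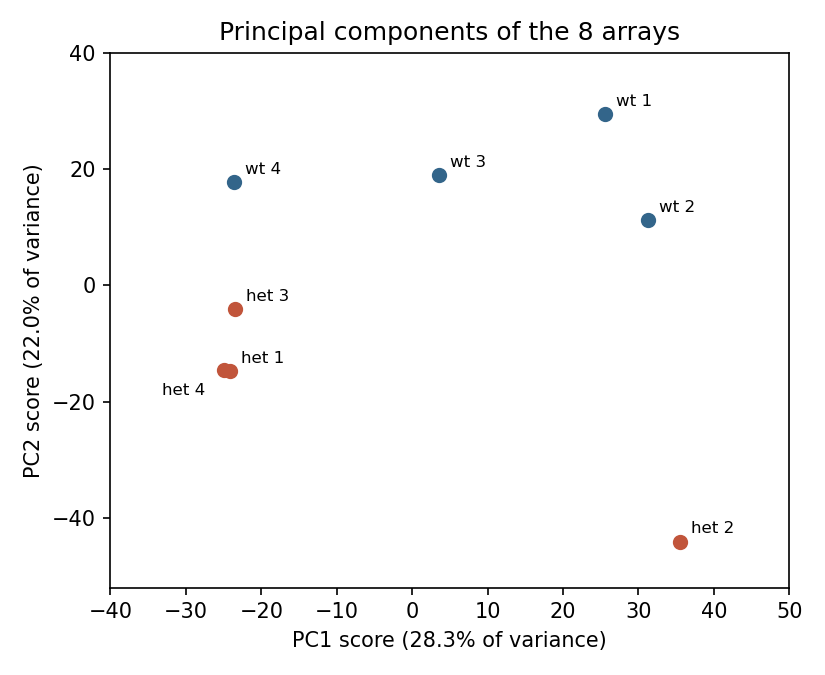
Scores of the 8 arrays on the first (horizontal) and second (vertical) principal component of all non-control probe sets, 1 point per array, with heterozygous (het) and wild-type (wt) replicate numbers. Wild-type replicate 4 scores with heterozygous replicates 1, 3 and 4 near -24 on the first component, and heterozygous replicate 2 lies at -44.12 on the second.

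Lists of pathways next to the lost enzyme were not called in the fit as planned. In the list of other methionine salvage genes 0 of 7 measured members passed (median log2 change -0.07, camera adjusted p = 0.731), and 0 passed when adjusted over the list alone. Polyamine genes were not shifted as a list (11 members, adjusted p = 0.968). Sat1, the enzyme that acetylates spermidine and spermine, was the sole member past 0.05 adjusted over the list alone (0.77, adjusted p = 0.234 over all genes). In the methionine cycle (17 members, camera adjusted p = 0.0626) this held for Bhmt, which remethylates homocysteine (-0.43, adjusted p = 0.234 over all genes). Arginine methylation genes (adjusted p = 0.233), with Prmt5 at -0.36, and purine genes (adjusted p = 0.189), with Ada at -0.53, had no member past either threshold. The methionine cycle list was called lower under 5 of 19 alternatives, with adjusted p from 0.00493 to 0.262 over all of them, including 0.00829 without heterozygous replicate 2, 0.0390 without wild-type replicate 1 and 0.0152 without wild-type replicate 2. The purine list was called lower under 2 of 19, with array weights (0.0413) and without heterozygous replicate 2 (0.0221). Fry for either direction called the methionine cycle (adjusted p = 0.0262) and polyamine (0.0452) lists.

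Camera with the preset correlation called 15 of the 40 lists, 7 higher and 8 lower. With an estimated correlation 0 of the 40 were called, as with fry for one direction, while fry for either direction called 14. Among all these lists the sole member past the threshold over all genes, apart from the window around Mtap, was Dnajb9. Camera's calls below therefore rest on the preset correlation. With the clock score covariate 7 of the 15 calls ended, while the mean change grew by over 1.5 times for acute phase (0.76 to 1.77), macrophage (0.25 to 0.77), interferon (0.16 to 0.50), pericentral (-0.28 to -0.48) and xenobiotic genes (-0.22 to -0.42).

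**Figure D3:**
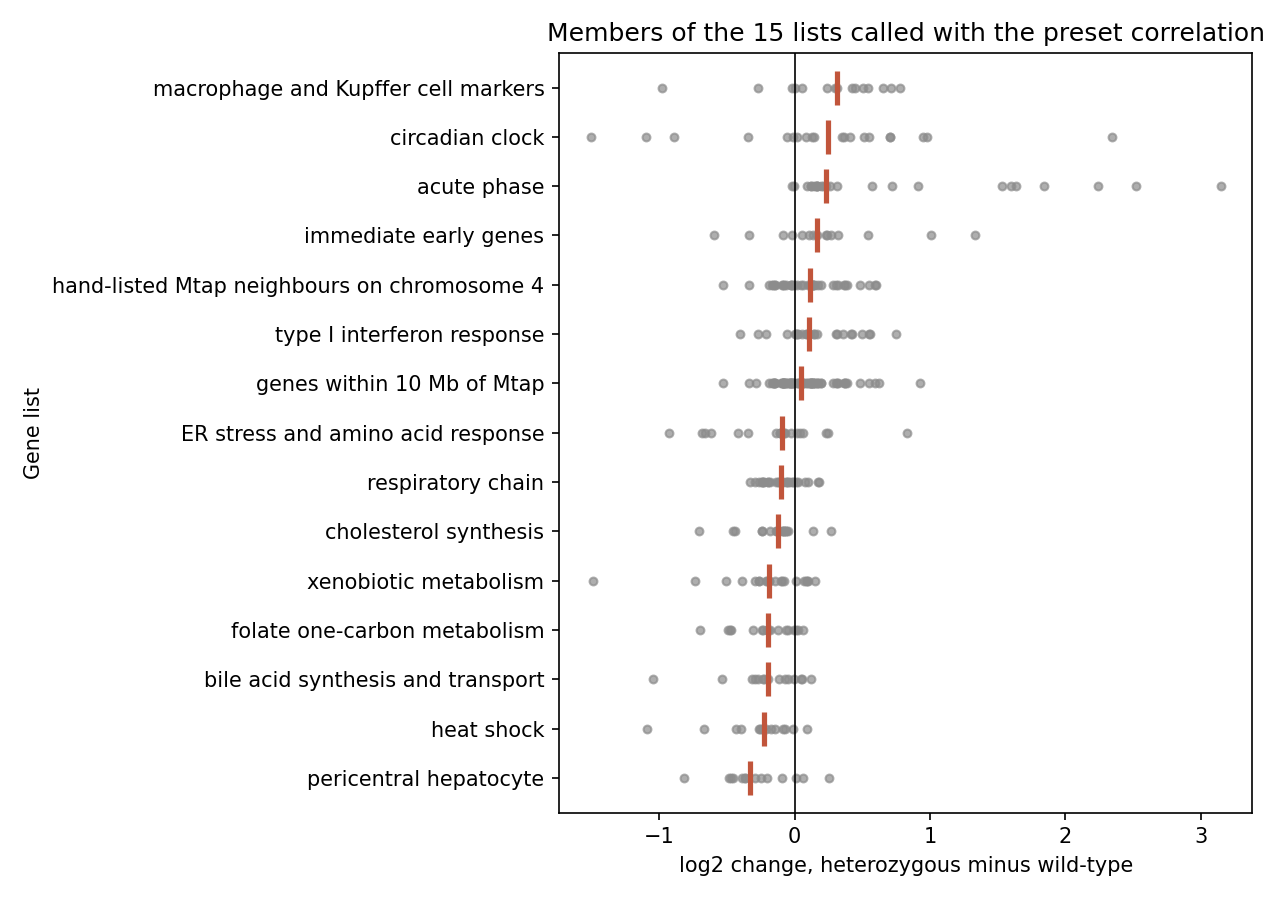
Log2 change, heterozygous minus wild-type (horizontal axis), of every measured member (grey points) of the 15 lists that camera called with the preset correlation (vertical axis), with the list median as a red bar. Medians run from -0.33 for pericentral genes to 0.31 for macrophage markers, and single acute phase and clock genes lie far from their medians.

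Inflammation-related lists were higher in heterozygous liver. Of 25 acute phase genes 23 were higher (median 0.23, mean 0.76, adjusted p = 6.61e-10, adjusted p = 0.342 with an estimated correlation), 0 passed over all genes and 6 passed adjusted over the list alone. These included the metallothioneins Mt1 (3.15 ± 0.62, SE) and Mt2 (2.52 ± 0.63), which bind zinc and copper, Socs3 (1.84 ± 0.45), a brake on cytokine signalling, and Saa3 (1.64 ± 0.51, from 1.005 to 2.03 when 1 array was left out). The mean over all 25 genes was 10.44 ± 0.47 (SD, n = 4) in heterozygous and 9.68 ± 0.26 in wild-type liver (exact permutation p = 0.0571), with heterozygous replicate 1 (9.92) below wild-type replicate 1 (10.04). The mean of serum amyloid and Lcn2 genes was 9.70 ± 1.75 and 7.95 ± 1.08 (exact permutation p = 0.171). The metallothionein mean was 8.96 ± 1.61 (SD, n = 4) in heterozygous and 6.13 ± 0.33 in wild-type liver (exact permutation p = 0.0286). Macrophage and Kupffer cell markers had 12 of 15 members higher (median 0.31, adjusted p = 0.000769, adjusted p = 0.364 with an estimated correlation), and Mpeg1 (0.65) was the 1 member past 0.05 adjusted over the list alone. The largest change of that list went the other way, in Cd163 (-0.98 ± 0.50, SE, adjusted p = 0.602; -0.38 without heterozygous replicate 2). Immediate early genes had 11 of 15 higher (median 0.16, adjusted p = 0.00361, adjusted p = 0.342 with an estimated correlation), with 4 past 0.05 adjusted over the list alone, namely Fos (1.34), Egr1 (1.01), Junb (0.54) and Ier3 (0.32), while Dusp1 was at -0.60 (-0.86 to -0.14 when 1 array was left out). The list's adjusted p was 0.0509 with dim genes left out and 0.0558 with the clock score covariate. Interferon response genes had 22 of 26 higher (median 0.10, adjusted p = 0.00403, adjusted p = 0.389 with an estimated correlation) and 0 past 0.05 adjusted over the list alone. Ifit1 was at 0.49 and Stat2, against the direction of the list, at -0.40. The interferon list's adjusted p was 0.0745 without wild-type replicate 4.

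Clock genes differed in both directions. Of 20 measured members 0 passed over all genes and 11 passed adjusted over the list alone, 7 higher and 4 lower (median 0.25, camera adjusted p = 0.0131, adjusted p = 0.369 with an estimated correlation). Dbp was higher by 2.35 ± 0.56 (SE), Per3 by 0.98 ± 0.17, Nr1d2 by 0.95 ± 0.28 and Tef by 0.71 ± 0.19. Arntl, which encodes the clock activator BMAL1, was at -1.51 ± 0.26, Nfil3 at -1.10 ± 0.22 and Cry1 at -0.89 ± 0.21. The clock score was 1.45 ± 0.50 (SD, n = 4) in heterozygous and 0.0694 ± 0.337 in wild-type liver (exact permutation p = 0.0286). Heterozygous replicate 4 (0.721) and wild-type replicate 4 (0.507) were close to each other. The list's adjusted p was 0.0615 without heterozygous replicate 1 and 0.0710 without wild-type replicate 4.

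**Figure D4:**
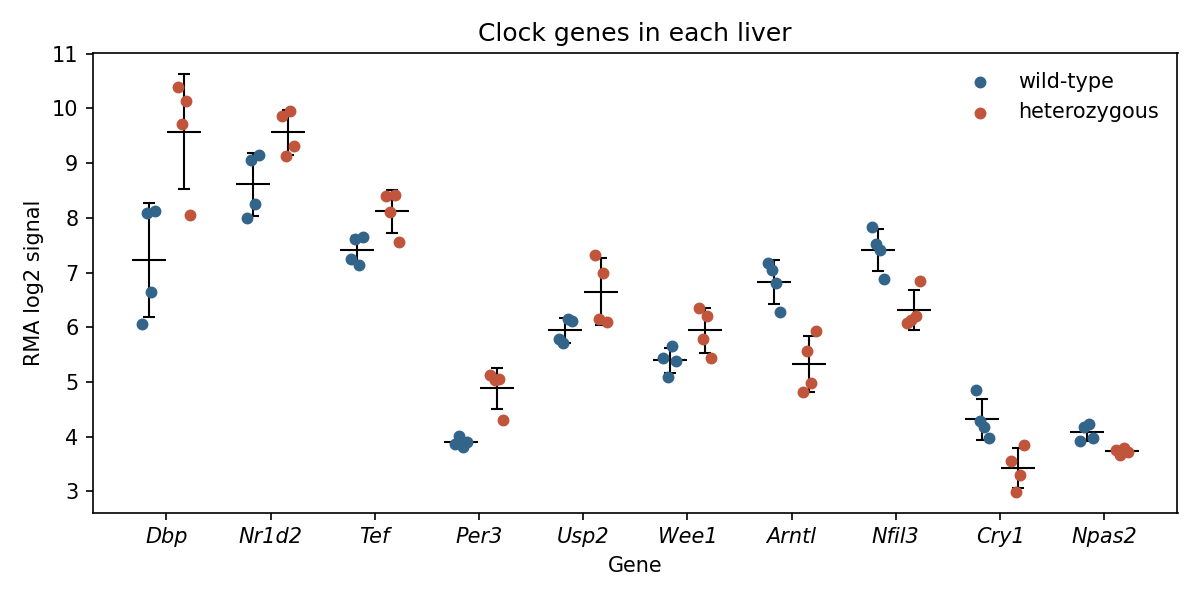
RMA log2 signal (vertical axis) of 10 clock genes (horizontal axis) in each liver, with points for animals and bars for the group mean and SD (n = 4). Dbp is higher by 2.35 and Arntl lower at -1.51 on average, and the heterozygous Dbp values range from 8.05 to 10.40.

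Chaperone and secretory stress genes were lower. Of 14 heat shock genes 13 were lower (median -0.23, adjusted p = 0.00066, adjusted p = 0.342 with an estimated correlation), and 4 passed adjusted over the list alone, Hsph1 (-0.67), Hspa1b (-1.09), Hspa1a (-0.44) and Dnajb1 (-0.40). Genes of endoplasmic reticulum stress and amino acid response had 13 of 19 lower (median -0.09, adjusted p = 0.0156, adjusted p = 0.369 with an estimated correlation). Dnajb9 passed over all genes and 5 members passed adjusted over the list alone, all of them lower, with Manf (-0.66), Creld2 (-0.68) and Hspa5 (-0.61) next, though the call of Dnajb9 was lost under 12 of 19 alternatives. Among the 6 higher members Asns, of the amino acid response, had the second largest change of the list in either direction (0.83 ± 0.40, SE, adjusted p = 0.585, from 0.54 to 1.09 when 1 array was left out), so the shift was not shared by the whole list. This list had an adjusted p of 0.0900 without heterozygous replicate 1, 0.0987 without wild-type replicate 2, 0.128 with the array split as a block, 0.0542 with the 3' minus 5' covariate and 0.0748 with the clock score covariate.

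Several metabolic lists were lower. Pericentral hepatocyte genes, expressed around the central vein, had 11 of 14 lower (median -0.33, adjusted p = 0.000769, adjusted p = 0.342 with an estimated correlation), and 4 passed adjusted over the list alone, Rhbg (-0.82), Gulo (-0.46), Axin2 (-0.47) and Cyp1a2 (-0.39). The 3 higher pericentral members changed by 0.01, 0.06 and 0.26, and 1 of them had an unadjusted p under 0.05 by limma. Periportal genes were not shifted (12 members, adjusted p = 0.994). Folate genes had 14 of 17 lower (median -0.20, adjusted p = 0.000769, adjusted p = 0.342 with an estimated correlation), and Fpgs (-0.47), Dmgdh (-0.49), Gldc (-0.70) and Shmt2 (-0.48) passed adjusted over the list alone. The folate list had an adjusted p of 0.0789 with the array split as a block and 0.134 with the clock score covariate. Xenobiotic genes had 15 of 21 lower (median -0.19, adjusted p = 0.0097, adjusted p = 0.369 with an estimated correlation), with Cyp2b10 (-1.49), the receptor gene Nr1i3 (-0.73) and Cyp1a2 past 0.05 adjusted over the list alone. Its adjusted p was 0.0783 without wild-type replicate 3. The xenobiotic list shares Cyp1a2 and further members with the pericentral list, so their calls are not fully separate evidence.

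Cholesterol synthesis genes had 17 of 19 lower (median -0.12, adjusted p = 0.0131, adjusted p = 0.389 with an estimated correlation), with Mvd (-0.71) and Mvk (-0.46) past 0.05 adjusted over the list alone. The adjusted p was 0.130 without wild-type replicate 3, 0.102 with the array split as a block and 0.0558 with the clock score covariate. Bile acid genes had 12 of 15 lower (median -0.20, adjusted p = 0.0154, adjusted p = 0.342 with an estimated correlation) and 0 past 0.05 adjusted over the list alone, with Cyp8b1, the sterol 12-hydroxylase, at -1.05 (-1.29 to -0.61 when 1 array was left out). Their adjusted p was 0.0619 without heterozygous replicate 2, 0.0960 without wild-type replicate 3 and 0.0545 without wild-type replicate 4. Respiratory chain genes had 22 of 28 lower (median -0.10, adjusted p = 0.0202, adjusted p = 0.342 with an estimated correlation) and 0 past 0.05 adjusted over the list alone. That call ended with renewed quantile normalisation (adjusted p = 0.0989), with the mean of a gene's probe sets (0.0503), with cross-hybridising kinds left out (0.0680), and without heterozygous replicate 4 (0.0660), wild-type replicate 3 (0.0559) or wild-type replicate 4 (0.0698).

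Other lists were not called in the main fit, though several were under some alternatives. Fatty acid synthesis had a median of 0.05 and a mean of -0.02 (adjusted p = 0.738), and was called higher with the array split as a block (mean 0.25, adjusted p = 5.67e-05) and lower without heterozygous replicate 2 (mean -0.20, adjusted p = 0.0461). Cell cycle genes had a mean of -0.10 (adjusted p = 0.731) and were also called in both directions, higher with that block (0.17, adjusted p = 0.00665) and with the clock score covariate (0.29, 0.0425), and lower with array weights (-0.27, 0.0325) and without heterozygous replicate 2 (-0.25, 0.0431). Male-biased genes had an adjusted p of 0.180, with Elovl3 at -1.04, and were called lower under 4 of 19 alternatives, with that block (0.000341), with the 3' minus 5' covariate (0.0221), without heterozygous replicate 1 (0.0447) and without heterozygous replicate 3 (0.0342). Adjusted p-values were 0.672 for fatty acid oxidation, 0.189 for glucose metabolism, 0.562 for female-biased genes, 0.113 for nucleolar and MYC target genes, 0.968 for p53 targets, 0.359 for NRF2 and glutathione genes, 0.243 for ribosomal proteins and 0.256 for fetal liver genes, of which Cd24a was at 1.52. Of these, nucleolar genes were called lower without heterozygous replicate 2 (0.0066) and without wild-type replicate 4 (0.0295), glucose genes lower without wild-type replicate 1 (0.0468) and with the clock score covariate (0.0188), and ribosomal proteins higher with the clock score covariate (0.0425). Fry for either direction called fatty acid oxidation (adjusted p = 0.0101) and glucose genes (0.00553). Among markers of other cell types the camera adjusted p-values were 0.0635 for lymphocytes, 0.562 for neutrophils, 0.256 for endothelium, 0.150 for stellate cells, 0.561 for cholangiocytes, 0.320 for erythroid cells, 0.343 for pancreatic acinar cells and 0.562 for adipose tissue. Lymphocyte markers were called higher under 6 of 18 alternatives, with adjusted p from 0.0155 without heterozygous replicate 3 to 0.0458 without wild-type replicate 3, and stellate cell markers under 3 of 19, with the mean of a gene's probe sets (0.0346), without wild-type replicate 1 (0.0261) and with the clock score covariate (0.0011).

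Genes around Mtap on chromosome 4 were examined because a targeted allele can carry flanking DNA of another strain. Of 73 measured genes within 10 Mb, neighbours being taken from assembly GRCm38.p6, 2310067E19Rik passed over all genes and 4 passed adjusted over the window alone, the others being Mpdz (0.63), Ttc39b (0.60) and Zdhhc21 (0.55). The other 2310067E19Rik probe set changed by 0.28 (adjusted p = 0.717 over all probe sets). Rps6 was at -0.53, Dennd4c at 0.32, Zfp352 at 0.32, Nfia at 0.39, Klhl9 at 0.31 and Eqtn at -0.29. The window as a list was higher (median 0.05, adjusted p = 0.0131, adjusted p = 0.369 with an estimated correlation), as were the 39 hand-listed chromosome 4 genes (median 0.12, adjusted p = 0.0103, adjusted p = 0.364 with an estimated correlation), of which 24 were higher and 15 lower, and 4 passed adjusted over the list alone, Mob3b (0.60), Ttc39b and Zdhhc21 higher and Rps6 lower. Mob3b lies outside the window, and all other hand-listed genes lie in it, so the hand list is no separate evidence. With the array split as a block the adjusted p-values of window and hand list were 0.128 and 0.0789, and with the clock score covariate 0.0694 and 0.134. Their mean changes of 0.076 and 0.099 shrank to 0.031 and 0.045 with the block, but were 0.085 and 0.087 with the clock score. The window's was 0.0660 without heterozygous replicate 4 and 0.0580 without wild-type replicate 1. A window of 20 Mb held 2 called genes, the second being Megf9, and a window of 5 Mb held 0 called genes by limma and 4 at an unadjusted p under 0.05. Fry for either direction called the 10 Mb window (adjusted p = 0.000161) and the hand list (0.0111). Fry for one direction called neither (adjusted p = 0.257 and 0.239).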

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

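The tests in this part of RNA integrity, hybridisation and timing against the array structure, of the array structure against clock and neighbouring genes, of clock arms within groups, and of single probe sets near Mtap were chosen after the result was seen.

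Chance was not excluded for any of the counts. Among all 35 splits of the 8 arrays into 4 and 4, 2 gave at least the 9 genes of the genotype split, with 215 in the highest other. The 16 probe sets were reached by 2 splits, with 513 in the highest other, the 15 called lists by 3 splits, with 15 in the highest other, and the 1 called gene near Mtap by 2 splits, with 1 in the highest other.

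The first pattern is the array structure. The split with 215 genes sets heterozygous replicates 1, 3 and 4 and wild-type replicate 4 against the rest and calls many times the genotype count, which points to a structure of the samples that is 3 to 1 confounded with genotype. The first principal component correlated with the 3' minus 5' control signal (Pearson r = -0.811, exact permutation p = 0.00975; Spearman rho = -0.738, p = 0.0458; r = -0.924 without the 2 farthest arrays), with the mean of 9 hybridisation control probe sets (r = -0.812, p = 0.0206; rho = -0.762, p = 0.0368; r = -0.697) and with the clock score (r = -0.406, p = 0.301; rho = -0.429, p = 0.299; r = -0.0156). In all 6 Pearson correlations were run, and adjusted over them these p-values were 0.0585, 0.0618 and 0.301, so none passed. On the component of representative probe sets alone r was -0.659, -0.656 and -0.646 (exact p = 0.068, 0.0892 and 0.0923). There Spearman rho was -0.714, -0.524 and -0.738 (exact permutation p = 0.0576, 0.197 and 0.0458, unadjusted). On that component wild-type replicate 4 scored -8.11, apart from heterozygous replicates 1, 3 and 4 (-19.52 to -16.52). Since 4 arrays sit together near -24 on the component of all probe sets, a pooled r may rest on that cluster. RNA integrity, hybridisation and animal state cannot be told apart with 8 arrays and no recorded batch. With the split as a block 4 genes were called, all among the 9, while 81 probe sets were, a rise that a block picked by its count of called genes could give by its construction.

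The second pattern is the clock genes, of which 12 had an unadjusted p under 0.05, with a median size of 0.799 log2 units. RNA quality that differs between genotypes stays open. The mean 3' minus 5' signal differed by 0.0447 (exact permutation p = 0.743), but heterozygous replicate 2 (0.713) held its group's mean down. Heterozygous replicates 1, 3 and 4 (1.10, 1.12 and 1.08) lay above all wild-type arrays (0.880 to 1.04). With that signal as a covariate the clock list's mean change was 0.203 against 0.217. With the split as a block the median ratio of the 12 clock genes' log2 changes to those without was 0.896. That shows little dependence on this split, but such a block cannot cover differences within its sides, so the array structure stays open too. Animals taken at different times of day may give such a pattern; within groups the evening and night arms correlated at -0.647 (permutation p = 0.125 over 576 arrangements), which does not decide it. Collection times were not given in the sources used here, so time of day and a genotype effect on the clock cannot be told apart. With the clock score as a covariate Megf9 was at 3.46 ± 0.51 (SE) against 2.88 ± 0.25 and Upp2 at 1.05 ± 0.39 against 1.62 ± 0.20, so the calls ended in part because the covariate, with no overlap between the genotypes, raised the errors.

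The third pattern is the genes near Mtap, where 10 in the window had an unadjusted p under 0.05, more than in 87.6% of windows of the same kind on other chromosomes. Faulty single probe sets are argued against for Mpdz and Ttc39b, of which 5 other probe sets moved the same way, but not for 2310067E19Rik and Zdhhc21, with 0 such probe sets. Chromosome 4 held 3 of the 9 called genes, Mtap, Megf9 and 2310067E19Rik, and 10 of its 1095 genes (0.913%), Mtap and the clock gene Per3 among them, had an unadjusted p under 0.001, against 7 of 705 (0.993%) on chromosome 13. On every further chromosome that share was 0.619% (chromosome 5) or less, so chromosomes 4 and 13 both stood above the rest. Flanking strain DNA may explain the group, but neither these counts nor the window percentile single it out. Fry for either direction called the window (adjusted p = 0.000161), the lowest adjusted p of that test among all lists. That test shows changes among window genes in either direction, but it does not tell strain DNA from other causes. The labels give no strain of the targeted cells. The timing difference and the array structure stay open as well, since the median ratio of the window's changes was 0.637 with the clock score and 0.791 with the split as a block.

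In 376 groups of 4 animals, 22 held a value far from the other 3 by Dixon's criterion, where chance gives 18.8. In heterozygous replicate 4 Per3 was low (4.31), and Clpx (9.90) and Nfil3 (6.85) were high. In heterozygous replicate 2 Rpl8 was high (12), Lrat (6.57), Klhl9 (8.25) and Cd163 (4.33) were low, and the 3' minus 5' signal was low for Actb (1.27), Gapdh (0.158) and their mean (0.713). In wild-type replicate 1 Clpx (10.21) and Cidea (2.37) were low and Rhbg (7.82) was high. In wild-type replicate 2 Cdo1 (12.36) and Sult3a1 (2.70) were high, and Sesn2 (5.79), Reln (7.99) and Alas2 (8.71) were low. In wild-type replicate 3 Trmt9b (5.03) and Fos (3.96) were low, and in wild-type replicate 4 Nop16 (7.31) was low and Nfia (8.80) high.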

How the results depend on the processing

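The clock score, the 3' minus 5' covariate and the array split as a block were chosen after seeing the data. The 9 called genes became 4 with the mean of a gene's probe sets, 2 with dim genes left out, 5 with treat, 306 at an unadjusted p under 0.05 and a fold of at least 1.5, 0 with the clock score and 4 with the array split as a block, and 3 to 20 with 1 array left out. The replicate numbers did not pair the animals (correlations of same-numbered deviations -0.07, 0.22, 0.00 and 0.23), and the replicate block gave 6 genes, 25 probe sets, 15 lists and 0 genes near Mtap. Mtap kept its direction throughout, at -0.80 with dim genes left out (adjusted p = 0.0589), -0.80 with the replicate block (0.112), -0.64 with the clock score (0.9999) and -0.79 with the array split (0.0915), with -0.84 to -0.74 when 1 array was left out and adjusted p from 0.0063 to 0.9999 over all its alternatives. The 1 called gene near Mtap became 0 with the mean of probe sets, dim genes left out, the clock score and a 5 Mb window, 2 with a 20 Mb window, and 0 to 1 with 1 array left out. The 15 lists became 0 with an estimated correlation and 0 with fry, and 12 to 19 with 1 array left out. The 16 probe sets became 81 with the array split and 42 with the 3' minus 5' signal, and 5 to 21 with 1 array left out. Camera's direction reversed for fatty acid synthesis, higher by camera at a mean of -0.02, without heterozygous replicate 2 (mean -0.20, called at an adjusted p of 0.0461). With another array left out the mean of that list reached up to 0.069, and no such fit called it (highest camera adjusted p 0.769). The direction also reversed with the clock score for the circadian clock (-0.12), cell cycle (0.29, called at 0.0425) and ribosomal proteins (0.14, called at 0.0425). With the array split it reversed for the cell cycle (0.17, called at 0.00665). With that split the mean of fatty acid synthesis was 0.25 and called, and uncalled means changed sign, among them those of nucleolar (0.005), NRF2 (0.032) and methionine salvage genes (0.036). The clock score ended the calls of the folate (adjusted p = 0.134), cholesterol (0.0558), circadian clock (0.330), endoplasmic reticulum stress (0.0748), immediate early (0.0558), hand-listed chromosome 4 (0.134) and Mtap window (0.0694) lists. Of these, mean changes grew for cholesterol (-0.152 to -0.177), immediate early (0.225 to 0.286) and window genes (0.076 to 0.085). They shrank for hand-listed (0.099 to 0.087), endoplasmic reticulum stress (-0.149 to -0.123) and folate genes (-0.214 to -0.151). The clock list's reversal follows from the covariate being built from its genes, and fewer arrays or residual degrees of freedom weaken tests by construction; otherwise the cause was not tested. Signal near background limits folds of dim probe sets.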

Other observations

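The test of macrophage RNA and the test of other cell types were chosen after the result was seen.

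Acute phase genes moved apart between animals. The mean of serum amyloid and Lcn2 genes was 11.66 in heterozygous replicate 4 and 10.55 in heterozygous replicate 3, but 7.71 in heterozygous replicate 1, and 9.51 in wild-type replicate 1 against 7.06 to 7.80 in the other wild-type livers (exact permutation p = 0.171). Metallothioneins were higher in all 4 heterozygous livers, from 7.17 to 10.72, than in wild-type livers, from 5.73 to 6.42.

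A stronger inflammatory state in some animals may account for the acute phase shift as a hypothesis, but within groups the serum amyloid and metallothionein means correlated at 0.369 (permutation p = 0.446), which leaves it open. Timing as measured by the clock score is argued against, since within groups the acute phase mean fell with it (r = -0.815, permutation p = 0.0382), opposite to the difference between genotypes. That p is unadjusted, and heterozygous replicate 4 weighs heavily in it. This liver had the highest acute phase mean (11.03) and the lowest heterozygous clock score (0.721), so collection time itself is not settled. A larger share of macrophage RNA also stays open, since the median change of macrophage markers (0.314) lay above that of acute phase genes (0.231) by 0.0837, less than 2 standard errors of the difference of the means over members (0.432), while the means lay the other way (0.247 and 0.762), by more than that, through a few acute phase genes with large changes. For the clock genes, another share of RNA from other cells stays open where they were higher. The largest median change of a marker list was 0.314, below the median size of 0.464 over all 20 clock genes but not decisively. The evening-phase mean changed by 0.603 (95% interval 0.209 to 0.996), which covers 0.314. For the night-phase genes as a set the values argue against such a share, with a mean change of -0.780 (95% interval -1.197 to -0.363). Pericentral (-0.276) and periportal (-0.057) gene means and the lowest marker mean (-0.077, pancreatic acinar) all lay outside that interval.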
